A study of Oryza sativa with 18 samples.

How the data were processed

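Total RNA of rice leaf sheath was hybridised to Affymetrix rice arrays with 57381 probe sets, 3 arrays for each of 6 groups. Per the labels, leaf sheath was taken from plants about 3 weeks old, grown in a chamber, and the RNA was labelled with a 3' IVT Express kit. The submitters' processing notes name MAS5, with no version. The deposited values are log2 MAS5 signals, and the log base, scaling and lower end were read from the values themselves. With 2 as the base, the mean of the linear signals, trimmed by 2% at each end, lay between 500.067 and 500.079 on the 18 arrays. The lowest value was 0, held by 270 to 701 probe sets per array, and array medians lay between 5.67 and 6.02. No quantile normalization by the authors was visible. Other steps are not given in the sources used here. The number of arrays limits the precision.

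The groups and replicates were taken from the titles and source names. The 123 control probe sets were left out, which left 57258, and 32732 were kept because at least 3 arrays exceeded the overall median of 5.78. No presence calls were used. Values near or under that level are imprecise. A platform annotation gave exactly 1 gene for 22436 probe sets, several for 95 and none for 34850. It covered 17905 genes, all found in a RefSeq gene table, which was used for names and gene order alone, and 2458 of these had a name other than a locus or clone number.

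In R 4.3.3, limma 3.58.1 fitted a mean for each group over all 18 arrays, with moderated variances and an intensity trend. It tested 9 comparisons: the lines at each of 3 times, each line at 6 h and 48 h against 0 h, and the difference between the lines' changes. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 32732, separately for each comparison. All changes are on the log2 scale, with the first line or the later time minus the other. Where probe sets of neighbouring or family genes share sequence, signal may be shared, and this was not tested.

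Gene lists were tested with camera in limma, on 1 probe set per gene (16404 genes, the probe set with the highest mean) and with a preset correlation of 0.01. Adjustment covered all 270 tests of 30 lists, out of 34 lists, since lists with under 5 measured members were not tested. Each test was repeated with the correlation estimated from the data. Lists covered hormone and defence signalling, cell wall, photosynthesis, growth, metabolism, the clock, other tissues and reference genes. WRKY genes are shared with the salicylate list and some cell wall genes with the vascular list, so these calls are not independent.

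For each comparison the genes named were the 8 largest rises and the 8 largest falls among called probe sets with 1 named gene and no overlap between the compared groups. Chance gives no overlap for 10% of probe sets with 3 arrays against 3, and the overlap was not asked of differences of responses. Up to 4 called members with the largest change were added from each list past its test and from 8 lists of defence, hormone and wall genes. Where this gave over about 30 genes, the first of each group by size are given.

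Comparisons, tests, thresholds, list topics, the rule for named genes and most alternatives were fixed before the data were examined. The member patterns of the lists were rewritten as gene names after the annotation had been seen. They were tightened once more after counts of called probe sets and the identifiers of the top ones had been seen, but before any list was tested. Alternatives covered quantile normalization, median centring, no or a stricter intensity filter, no trend, a replicate block, the compared groups alone, a minimum of 2-fold, and leaving out each array. An offset before the logarithm had been planned for linear values and so was run as an added alternative, with the 20th percentile of all signals, 9.66. Array weights and a covariate for the 3' to 5' difference of control probe sets were also added after the data had been seen. The method was tested on simulated data with the spread of these arrays. Log2 changes of 1 and 2 were put into 100 probe sets each for the response of NIL-Bph6-RNAi at 48 h. The method recovered 39 and 75, with 6 false calls. With so few changed, this does not carry over to the real 10911 calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and figures.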

Results

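Transcript levels were measured in rice leaf sheath on 18 Affymetrix rice arrays, 3 for each of 6 groups. The plants belonged to NIL-Bph6, a near-isogenic line carrying the planthopper resistance gene Bph6, or to NIL-Bph6-RNAi, which the labels call susceptible. By its name the latter is that line with an RNAi construct. Genome segments may also differ between the lines, as given at the end. Sheaths were taken before feeding by the brown planthopper, a phloem-feeding insect pest of rice, and after 6 h and 48 h of it. The replicates of a group are labelled as biological. Titles, source names and the series design gave these lines and times, whereas the description fields named another cultivar and NIL-BPH9 with times of 0, 3 and 6 h, and the groups were taken from the former. The questions were how the lines differed at each time, how each changed from 0 h, and whether these changes differed between lines. No plants kept for 6 h or 48 h without insects were analysed here, so each change from 0 h also includes whatever else differed between these times. The number of arrays limits the precision. The probe set for the targeted gene itself was not analysed here.

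The labels were checked with the 64 probe sets that the array carries for reporter and marker genes. Of these, 1 was higher on each of the 9 NIL-Bph6-RNAi arrays than on each of the 9 NIL-Bph6 arrays, at 11.85 to 13.15 against 0.97 to 5.44 log2 signal, and 0 were lower on each. Its group means at 0 h were 12.43 ± 0.22 and 2.51 ± 1.76 (SD, n = 3). Arrays of a group correlated with each other at a mean r of 0.950 to 0.964 across probe sets, which are not independent replicates, and 17 of 18 arrays correlated best with an array of their own group. NIL-Bph6-RNAi 48 h replicate 3 stood farthest from the other groups, with a mean r of 0.903 to them. The mean difference between 3' and 5' control probe sets, a sign of RNA quality, was 1.49 ± 0.71 (SD, n = 3) at 0 h in NIL-Bph6 and 2.41 ± 0.36 in NIL-Bph6-RNAi. In the other 4 groups it lay between 1.88 and 2.08.

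**Figure D1:**
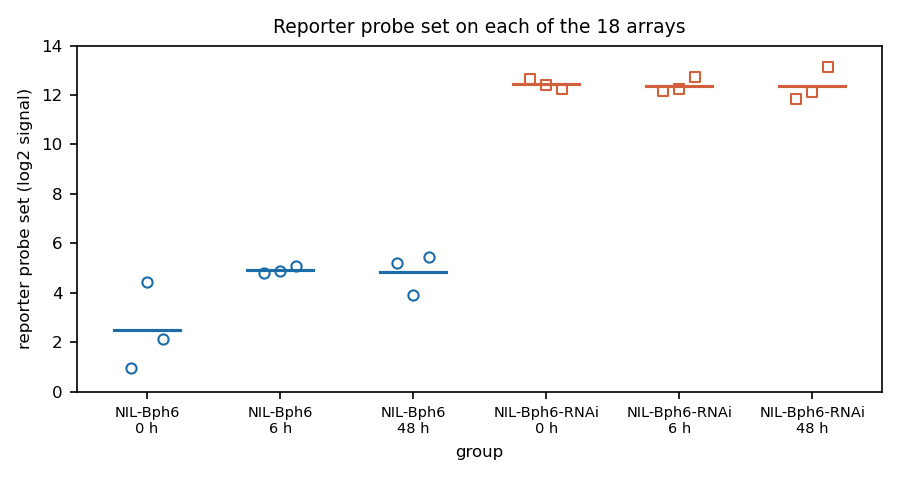
Log2 signal of the reporter probe set on each of the 18 arrays by group, with points for arrays and lines for group means. All 9 NIL-Bph6-RNAi arrays lie at 11.85 or above and all 9 NIL-Bph6 arrays at 5.44 or below.

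Before feeding, the diterpene cyclase gene KSL7 (LOC4329724) was higher in NIL-Bph6 than in NIL-Bph6-RNAi by 2.49 ± 0.60 (adjusted p = 0.0492) on the log2 scale (± SE, n = 3 per group, as in all values below). The nicotianamine synthase gene NAS1 (LOC4332608) was higher by 2.15 ± 0.34 (adjusted p = 0.00216) and the metallothionein gene MT1B (LOC4332487) by 1.98 ± 0.37 (adjusted p = 0.0106). The auxin-conjugating enzyme gene GH3.2 (LOC4326893) was higher by 1.94 ± 0.40 (adjusted p = 0.0201) and the argonaute gene AGO18 (LOC4343201) by 1.76 ± 0.24 (adjusted p = 0.00056). DREB1B (LOC4347618), a transcription factor gene of the cold-response family, stood at 7.91 ± 0.46 against 6.11 ± 0.38 (SD). Lower in NIL-Bph6 were the chitinase gene Cht1 (LOC4338719) at -2.86 ± 0.65 (adjusted p = 0.0362), from means of 4.95 ± 0.34 and 7.81 ± 0.08 (SD), and the sugar transporter gene SWEET16 (LOC4332795) at -1.99 ± 0.30 (adjusted p = 0.00168). So were the germin-like gene GER2 (LOC4344839) at -1.27 ± 0.27 and the chitin receptor kinase gene CERK1 (LOC4346173) at -0.66 ± 0.12. Also called were LPR2 at 1.57 ± 0.31 and GH3.4 (LOC4339234) at 1.49 ± 0.30, from 6.85 ± 0.34 against 5.36 ± 0.21 (SD). The MADS-box gene AGL20 (LOC4331445) was lower at -0.70 ± 0.14, HOX5 (LOC4345576) at -0.68 ± 0.16 and CIN7 (LOC4346527) at -0.65 ± 0.11. Cht1 lies in a run of 11 measured genes, of which 8 differed at 0 h.

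Of the phytoalexin synthesis genes, 1 of 17 was higher and 0 were lower, or 9 and 0 adjusted over the list alone, with a median difference of 1.63. The phytoalexin list had camera adjusted p = 1.44e-05, and 0.632 with an estimated correlation. In the salicylate list, 1 of 17 was higher and 0 were lower, or 5 and 0 adjusted over the list alone. Camera gave the salicylate list adjusted p = 0.00561, and 0.62 with an estimated correlation. In the WRKY list, which overlaps with it, 1 of 6 was higher and 0 were lower, or 3 and 0 adjusted over the list alone, the member past the test being WRKY71 (LOC4328512) at 1.35 ± 0.25 (adjusted p = 0.0105). For the WRKY list camera gave adjusted p = 0.0129, and 0.62 with an estimated correlation. Among the cellulose synthase and wall-loosening genes, 0 of 65 were higher and 1 was lower, or 0 and 1 adjusted over the list alone, the single call being EXLA4 (LOC4342109) at -1.22 ± 0.28. The cell wall list had camera adjusted p = 1.28e-05, and 0.62 with an estimated correlation. Both remaining lists past the test at 0 h were shifted down. For phenylpropanoid synthesis 0 of 34 were higher and 0 were lower, or 1 and 0 adjusted over the list alone. Camera gave the phenylpropanoid list adjusted p = 0.0326, and 0.713 with an estimated correlation. By array its mean was 10.09, 10.39 and 9.61 in NIL-Bph6 against 10.09, 10.23 and 10.21 in NIL-Bph6-RNAi. By these means the downward shift rested on replicate 3 of the former. For carbon fixation and chlorophyll synthesis 0 of 21 were higher and 0 were lower, or 0 and 2 adjusted over the list alone. For the carbon fixation list camera gave adjusted p = 0.0047, and 0.62 with an estimated correlation. NINJA1, an adaptor of jasmonate repressors, was higher by 0.52 ± 0.09 (adjusted p = 0.00348).

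In limma, 460 of 32732 probe sets differed at 0 h, 282 higher and 178 lower in NIL-Bph6, and with median centring the split was 199 and 195. Without NIL-Bph6 0 h replicates 1, 2 and 3 in turn the count was 282, 850 and 233, the last with 113 higher and 120 lower, and without NIL-Bph6-RNAi 0 h replicates 2 and 3 it was 225 and 272. With only the compared groups in the fit it was 289, with the 3' to 5' difference as a covariate 221, and with array weights 5247. The phenylpropanoid call ended with quantile normalization, at adjusted p = 0.0781. The 0 h groups lay farthest apart in 3' to 5' difference. For genes given here whose call some alternative ended, the highest adjusted p was KSL7 at 0.228, GH3.2 at 0.131 and WRKY71 at 0.0794 without NIL-Bph6-RNAi 0 h replicate 2. MT1B reached 0.0751, DREB1B 0.0917, GER2 0.158, LPR2 0.093, HOX5 0.211 and EXLA4 0.189 without NIL-Bph6 0 h replicate 3. Cht1 reached 0.136 and GH3.4 0.099 without NIL-Bph6 0 h replicate 1. CERK1 reached 0.0584, AGL20 0.125, CIN7 0.0881 and NINJA1 0.0717 with only the compared groups in the fit.

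After 6 h of feeding, some jasmonate genes and the cold-response genes CBF3 (LOC4347620), DREB1B and DREB1G (LOC4330306) rose in NIL-Bph6. CBF3 rose by 4.11 ± 0.59 (adjusted p = 0.000886), DREB1B by 3.66 ± 0.35 (adjusted p = 6.09e-05) and DREB1G by 3.49 ± 0.37. Among jasmonate genes, the repressor genes JAZ9 (LOC4331832), JAZ13 (LOC4348531) and JAZ12 (LOC4348533) rose by 3.36 ± 0.60, 3.05 ± 0.50 and 1.92 ± 0.30, and the transcription factor gene BHLH148 (LOC4334060) by 3.16 ± 0.40 (adjusted p = 0.000354). In the jasmonate list, 12 of 32 rose and 0 fell, or 15 and 1 adjusted over the list alone. The jasmonate list had camera adjusted p = 1.34e-05, and 0.62 with an estimated correlation. The calcium sensor gene CBL4 (LOC4339432) changed by -1.11 ± 0.27 (adjusted p = 0.0257), the transporter genes BASS3 (LOC4329356) and SWEET1b (LOC4338851) by -1.10 ± 0.21 and -1.04 ± 0.24, and ADCS (LOC4341959) by -1.05 ± 0.29.

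The calcium signalling list had a median change of 0.06 in NIL-Bph6 at 6 h: 12 of 76 rose and 3 fell, or 17 and 4 adjusted over the list alone, with CML27 (LOC4332731) at 2.04 ± 0.28, CIPK14 (LOC4351307) at 1.81 ± 0.35 and CPK4 (LOC4328155) at 1.71 ± 0.24. Camera gave the calcium list adjusted p = 0.0465, and 0.62 with an estimated correlation. In the cell wall list, 7 of 65 rose and 0 fell, or 10 and 0 adjusted over the list alone, led by BC1L9 (LOC4349011) at 2.78 ± 0.38 and CSLA9 (LOC4341571) at 2.45 ± 0.53, the latter from 5.61 ± 1.09 (SD). For the cell wall list camera gave adjusted p = 0.000596, and 0.666 with an estimated correlation. Of the histone and cell cycle genes, 6 of 89 rose and 0 fell, or 24 and 2 adjusted over the list alone, with H2B.10 (LOC4324495) at 1.60 ± 0.35 (adjusted p = 0.0146) and the cyclin gene CYCA3-2 (LOC4352642) at 1.32 ± 0.31. The cell cycle list had camera adjusted p = 0.000544, and 0.713 with an estimated correlation. The shoot meristem list, whose called members were the growth-regulating factor genes GRF10 (LOC4330314) at 2.43 ± 0.36 (from 5.32 ± 0.66, SD), GRF1 (LOC4330903) at 1.89 ± 0.32 and GRF6 (LOC4333990) at 1.64 ± 0.38, shifted up, and 3 of 16 rose and 0 fell, or 5 and 0 adjusted over the list alone. Camera gave the meristem list adjusted p = 0.00622, and 0.62 with an estimated correlation. In the WRKY list 1 of 6 rose and 0 fell, or 3 and 0 adjusted over the list alone, with WRKY71 at 1.87 ± 0.25. For the WRKY list camera gave adjusted p = 0.00622, and 0.62 with an estimated correlation. The light reactions shifted down, where 0 of 14 rose and 1 fell, or 0 and 1 adjusted over the list alone, namely VIPP1 at -0.33 ± 0.09. The light reaction list had camera adjusted p = 0.0103, and 0.665 with an estimated correlation. Carbon fixation shifted down too, where 0 of 21 rose and 2 fell, or 0 and 3 adjusted over the list alone, PORB (LOC4349004) at -0.44 ± 0.11 among them. Camera gave the carbon fixation list adjusted p = 0.0094, and 0.624 with an estimated correlation. Ribosomal proteins, where 0 of 25 rose and 0 fell, or 0 and 0 adjusted over the list alone, moved the same way. For the ribosomal list camera gave adjusted p = 0.022, and 0.784 with an estimated correlation. Peroxidases and glutathione transferases shifted down as well, where 0 of 17 rose and 0 fell, or 0 and 1 adjusted over the list alone. The peroxidase list had camera adjusted p = 0.0436, and 0.62 with an estimated correlation.

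In all, 1675 probe sets changed in NIL-Bph6 at 6 h, 1152 up and 523 down, and 1040 up and 732 down with median centring. The count was 792 without NIL-Bph6 0 h replicate 1, and 828, 969 and 821 without NIL-Bph6 6 h replicates 1, 2 and 3. It was 8597 with array weights, 4260 up and 4337 down, and 865 when a change of at least 2-fold was also required. With quantile normalization the calls of the peroxidase, light reaction and ribosomal lists ended, at adjusted p = 0.0894, 0.213 and 0.24, and with all probe sets as members that of calcium signalling, at 0.0752. Genes given here that lost their call had a highest adjusted p of CBL4 at 0.101 without NIL-Bph6 0 h replicate 3. SWEET1b reached 0.1, ADCS 0.195, CYCA3-2 0.106 and GRF6 0.0847 without NIL-Bph6 6 h replicate 1. CSLA9 reached 0.0665 and H2B.10 0.0674 without NIL-Bph6 0 h replicate 1. VIPP1 reached 0.131 and PORB 0.122 without NIL-Bph6 6 h replicate 3.

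In NIL-Bph6-RNAi, CBF3 rose after 6 h by 5.71 ± 0.59 (adjusted p = 2.64e-05) from a low level of 4.38 ± 1.67 (SD), and DREB1B by 5.64 ± 0.35 (adjusted p = 6.16e-07). BHLH148 rose by 3.66 ± 0.40 (adjusted p = 4.22e-05) and the calmodulin-like gene CML31 (LOC4325408) by 3.59 ± 0.37 (adjusted p = 2.64e-05). Of the jasmonate genes, 10 of 32 rose and 0 fell, or 16 and 1 adjusted over the list alone, with JAZ13 at 3.21 ± 0.50 and JAZ9 at 2.99 ± 0.60. Camera gave the jasmonate list adjusted p = 6.95e-05, and 0.62 with an estimated correlation. MIF3 (LOC4347053) changed by -1.86 ± 0.46 (adjusted p = 0.0283), the lignin-pathway gene CAD3 (LOC4348690) by -1.19 ± 0.23 (adjusted p = 0.00633), the glycosyltransferase gene GT43A (LOC4337665) by -1.06 ± 0.26 and ENR (LOC4346596) by -1.06 ± 0.20.

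Some dehydration markers rose as well, with the abscisic acid hydroxylase gene ABA8OX1 (LOC9269675) at 2.94 ± 0.26 (adjusted p = 7.08e-06) and the dehydrin gene RAB21 (LOC4350454) at 2.84 ± 0.55. In that list, 4 of 32 rose and 0 fell, or 12 and 0 adjusted over the list alone. For the dehydration list camera gave adjusted p = 0.0094, and 0.62 with an estimated correlation. In the salicylate list 4 of 17 rose and 0 fell, or 6 and 0 adjusted over the list alone. The salicylate list had camera adjusted p = 0.000544, and 0.62 with an estimated correlation. In the WRKY list 2 of 6 rose and 0 fell, or 3 and 0 adjusted over the list alone, the members being WRKY24 (LOC4327518) at 3.41 ± 0.49 and WRKY71 at 3.19 ± 0.25. Camera gave the WRKY list adjusted p = 0.00151, and 0.62 with an estimated correlation. Of the calcium signalling genes, 13 of 76 rose and 0 fell, or 19 and 2 adjusted over the list alone. For the calcium list camera gave adjusted p = 0.0202, and 0.62 with an estimated correlation. Among ethylene genes, 4 of 11 rose and 0 fell, or 4 and 0 adjusted over the list alone, with the synthesis gene ACS2 (LOC4336750) at 1.49 ± 0.39 (adjusted p = 0.0367) and the transcription factor gene EIL1 (LOC4332697) at 1.20 ± 0.32. The ethylene list had camera adjusted p = 0.0415, and 0.62 with an estimated correlation. For pathogenesis-related genes 1 of 23 rose and 0 fell, or 5 and 0 adjusted over the list alone, the call being GLP2 (LOC4344846) at 1.45 ± 0.35. Camera gave the pathogenesis-related list adjusted p = 0.0447, and 0.707 with an estimated correlation. The phytoalexin list shifted up with a median of 1.52, while 0 of 17 rose and 0 fell, or 6 and 0 adjusted over the list alone. For the phytoalexin list camera gave adjusted p = 0.00858, and 0.738 with an estimated correlation. Shifted down were carbon fixation and chlorophyll synthesis, where 0 of 21 rose and 3 fell, or 0 and 7 adjusted over the list alone, GSA (LOC4346136) at -0.60 ± 0.11 among them. The carbon fixation list had camera adjusted p = 0.000294, and 0.62 with an estimated correlation. Ribosomal proteins, where 0 of 25 rose and 0 fell, or 0 and 0 adjusted over the list alone, shifted down too. Camera gave the ribosomal list adjusted p = 0.0132, and 0.782 with an estimated correlation.

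The response at 6 h in NIL-Bph6-RNAi comprised 1736 probe sets, 1210 up and 526 down, and 881 up and 774 down with median centring. Without NIL-Bph6-RNAi 0 h replicates 1, 2 and 3 the count was 1128, 669 and 902, and without NIL-Bph6-RNAi 6 h replicates 1 and 3 it was 990 and 885. Array weights gave 3941, and requiring a change of at least 2-fold gave 828. The ribosomal list lost its call with quantile normalization, at adjusted p = 0.307, and the ethylene list with all probe sets as members, at 0.0807. Genes given here whose call some alternative ended had a highest adjusted p of MIF3 at 0.127, ACS2 at 0.162, EIL1 at 0.197 and GLP2 at 0.133 without NIL-Bph6-RNAi 0 h replicate 2. GT43A reached 0.112 without NIL-Bph6-RNAi 6 h replicate 3.

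Of the 1152 probe sets that rose in NIL-Bph6 at 6 h, 489 also rose in NIL-Bph6-RNAi, where independent lists would share 42.6, and 40 of 523 fell in both, against 8.4. These comparisons share no arrays. Across probe sets, which are not independent, the 2 responses at 6 h correlated at r = 0.251. Tested directly, the responses at 6 h differed for 2 probe sets, chosen here after their values were seen: that of LOC4338474, at -1.82 ± 0.23, and that of LOC4337638, at -3.28 ± 0.43 (adjusted p = 0.0172 for both). The second changed by -0.47 in NIL-Bph6 and 2.82 in NIL-Bph6-RNAi. The first stood at 12.05 ± 0.30 (SD, n = 3) in NIL-Bph6 and 10.65 ± 0.11 in NIL-Bph6-RNAi at 0 h, and at 12.72 ± 0.18 and 13.14 ± 0.08 at 6 h. At an unadjusted p under 0.05 there were 4898. Without the trend in limma the count was 0, and it ranged from 0 to 53 when 1 array was left out, at 53 without NIL-Bph6 0 h replicate 2 and 14 without NIL-Bph6 6 h replicate 1. It was 1 without NIL-Bph6 0 h replicate 1 or 3, and 0 without NIL-Bph6 6 h replicate 2 or 3, NIL-Bph6-RNAi 0 h replicate 1 or 2, or any NIL-Bph6-RNAi 6 h replicate. With array weights it was 1066, with the 3' to 5' covariate 1, and with only the compared groups in the fit 5.

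As a whole, the cell wall list differed between the responses at 6 h, with a median difference of 0.49 and 0 single members past the test (camera adjusted p = 1.05e-06, adjusted p = 0.62 with an estimated correlation). Its median change was 0.25 in NIL-Bph6 and -0.16 in NIL-Bph6-RNAi, and between the lines its median was -0.37 at 0 h and 0.19 at 6 h, so much of the difference lay in the start. Histones and cell cycle differed likewise, at 0.36 (camera adjusted p = 0.000596, 0.713 with an estimated correlation). Much of this lay in NIL-Bph6-RNAi 6 h replicate 3. Shoot meristem markers also differed in that direction, at 0.38 (camera adjusted p = 0.0326, 0.62 with an estimated correlation). Epidermis and cuticle markers did too, at 0.36 (camera adjusted p = 0.0242, 0.62 with an estimated correlation). Phytoalexin synthesis went the other way, at -1.55 (camera adjusted p = 0.00145, adjusted p = 0.711 with an estimated correlation), after a start 1.63 higher in NIL-Bph6. Adjusted over the list alone, 2 meristem and 2 epidermis members passed, and 0 in the other 3 lists; limma gave 0 members in all 5 over all genes.

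At 6 h the levels of the lines differed for 282 probe sets, 103 higher and 179 lower in NIL-Bph6. H2B.10 was higher by 2.35 ± 0.35 (adjusted p = 0.00177), the succinate dehydrogenase gene SDH3-2 (LOC4343404) by 1.61 ± 0.15 (adjusted p = 7.69e-06), and AGO18 by 1.41 ± 0.24. The NPR1 homologue gene NH3 (LOC4333666) was higher by 0.85 ± 0.17 and NINJA1 by 0.74 ± 0.09 (adjusted p = 0.000116). The secretory carrier gene SCAMP3 (LOC4339247) and the porin genes VDAC5 (LOC4331978) and VDAC2 (LOC4339446) were higher by 0.80 ± 0.17, 0.60 ± 0.13 and 0.39 ± 0.08. Lower were Cht1 at -3.67 ± 0.65 (adjusted p = 0.00823), the beta-glucosidase gene BGLU13 (LOC4336146) at -1.92 ± 0.29 (adjusted p = 0.00181) and SWEET16 at -1.91 ± 0.30. So were AGL20 at -1.11 ± 0.14 (adjusted p = 0.000233), SWEET1b at -1.21 ± 0.24 and cap2 (LOC4331843) at -1.77 ± 0.40. CLPB1 (LOC4339343) stood at 4.74 ± 1.34 against 7.64 ± 0.14 (SD), METK3 (LOC4325163) at 5.60 ± 0.53 against 7.57 ± 0.83 and Cht1 at 4.04 ± 1.36 against 7.71 ± 0.92, partly in the imprecise range under 5.78. In the cell cycle list 1 of 89 was higher and 0 were lower, or 1 and 0 adjusted over the list alone. For the cell cycle list camera gave adjusted p = 0.00108, and 0.72 with an estimated correlation. In the light reactions 0 of 14 were higher and 1 was lower, or 0 and 1 adjusted over the list alone, namely LHCP (LOC4333359) at -0.65 ± 0.14. The light reaction list had camera adjusted p = 4.66e-06, and 0.62 with an estimated correlation. The cell wall list shifted up by a median of 0.19 (camera adjusted p = 0.022, 0.738 with an estimated correlation). By array its mean was 9.77, 9.77 and 9.74 in NIL-Bph6 against 9.62, 9.73 and 9.27 in NIL-Bph6-RNAi. Cell cycle means were 9.25, 9.06 and 9.01 against 8.99, 9.10 and 8.45. Much of both shifts thus lay in replicate 3 of NIL-Bph6-RNAi. Medians were 0.12 for the auxin response list (camera adjusted p = 0.023, adjusted p = 0.62 with an estimated correlation) and 0.49 for the meristem list (camera adjusted p = 0.0146, adjusted p = 0.62 with an estimated correlation). None of their 65, 60 and 16 members passed over all genes in limma, and 0, 1 and 1 did adjusted over the list alone. Of the probe sets lower in NIL-Bph6 at 0 h, 97 of 178 were also lower at 6 h, where chance gives 0.973, and 53 of 282 were higher at both times, against 0.887. The count at 6 h was 179 without NIL-Bph6 6 h replicate 2 and 727 with array weights. Genes that lost their call in an alternative had a highest adjusted p of AGO18 at 0.0559, NH3 at 0.145, SCAMP3 at 0.16, VDAC5 at 0.228, VDAC2 at 0.138, Cht1 at 0.0962, SWEET1b at 0.157 and CLPB1 at 0.111 with only the compared groups in the fit. cap2 reached 0.202 and METK3 0.167 without NIL-Bph6 6 h replicate 2. LHCP reached 0.152 without NIL-Bph6 6 h replicate 3.

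After 48 h, the cold-response genes DREB1B and CBF3, the glyoxylate cycle genes ICL (LOC4343441) and MS (LOC9268154) and some jasmonate genes were up in NIL-Bph6. DREB1B rose by 4.32 ± 0.35 (adjusted p = 6.34e-06) and CBF3 by 4.29 ± 0.59 (adjusted p = 0.000222). The isocitrate lyase gene ICL rose by 3.92 ± 0.53 (adjusted p = 0.000201) and the malate synthase gene MS by 3.83 ± 0.37 (adjusted p = 1.98e-05). BHLH148 rose by 3.57 ± 0.40 and JAZ13 by 3.10 ± 0.50. Of the jasmonate list 10 of 32 rose and 3 fell, or 10 and 4 adjusted over the list alone, and as a whole it did not pass. Camera gave the jasmonate list adjusted p = 0.0606, and 0.784 with an estimated correlation. The phenylpropanoid gene 4CL.2 (LOC4330407) changed by -2.30 ± 0.47 (adjusted p = 0.0032) and the beta-glucosidase gene BGLU19 (LOC4338556) by -1.76 ± 0.33 (adjusted p = 0.00159). PDX12 (LOC4347937) changed by -1.74 ± 0.27 and the diterpene synthesis gene KS6 (LOC4329728) by -1.69 ± 0.45.

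The light reaction and carbon fixation lists shifted down in NIL-Bph6 by 48 h. In the light reactions, 0 of 14 rose and 10 fell, or 0 and 13 adjusted over the list alone, among them PSB28 (LOC4326537) at -1.39 ± 0.28 and PSAG (LOC4337812) at -1.06 ± 0.23. For the light reaction list camera gave adjusted p = 2.93e-08, and 0.62 with an estimated correlation. In carbon fixation and chlorophyll synthesis 1 of 21 rose and 14 fell, or 1 and 18 adjusted over the list alone, with the fructose bisphosphatase gene CFBP1 (LOC4325071) at -1.44 ± 0.22 and OsrcaA1 (LOC4351224) at -1.08 ± 0.33. The carbon fixation list had camera adjusted p = 2.93e-08, and 0.62 with an estimated correlation. The histone and cell cycle list shifted up: 27 of 89 rose and 2 fell, or 38 and 4 adjusted over the list alone, with the cyclin gene CYCB2 (LOC4342121) at 2.37 ± 0.71 (adjusted p = 0.0315) and H2B.10 at 2.07 ± 0.35. Camera gave the cell cycle list adjusted p = 0.000294, and 0.707 with an estimated correlation. For the cell wall list 15 of 65 rose and 1 fell, or 17 and 1 adjusted over the list alone, with the expansin gene EXPA29 (LOC4342086) at 3.74 ± 1.11 and CSLA9 at 2.57 ± 0.53. For the cell wall list camera gave adjusted p = 0.015, and 0.738 with an estimated correlation. Of the pathogenesis-related genes, 6 of 23 rose and 0 fell, or 6 and 0 adjusted over the list alone, the chitinase gene Chib3H-a (LOC4351194) at 3.79 ± 0.53 and GER2 at 1.99 ± 0.27 among them. The pathogenesis-related list had camera adjusted p = 0.0242, and 0.666 with an estimated correlation. In the WRKY list, with WRKY24 at 2.25 ± 0.49, 3 of 6 rose and 0 fell, or 4 and 0 adjusted over the list alone. Camera gave the WRKY list adjusted p = 0.00586, and 0.62 with an estimated correlation. In the abscisic acid and dehydration list 9 of 32 rose and 0 fell, or 11 and 2 adjusted over the list alone, with ABA8OX1 at 2.82 ± 0.26 and LEA19 at 2.08 ± 0.59. For the dehydration list camera gave adjusted p = 0.022, and 0.62 with an estimated correlation. Called meristem, vascular and epidermis markers rose as well, although these lists did not pass in camera. In the meristem list 5 of 16 rose and 0 fell, or 6 and 1 adjusted over the list alone, with a median of 0.42. The meristem list had camera adjusted p = 0.0698, and 0.62 with an estimated correlation. Of vascular markers 2 of 13 rose and 0 fell, or 3 and 0 adjusted over the list alone. Camera gave the vascular list adjusted p = 0.302, and 0.738 with an estimated correlation. Of epidermis markers 3 of 12 rose and 0 fell, or 3 and 0 adjusted over the list alone. For the epidermis list camera gave adjusted p = 0.33, and 0.784 with an estimated correlation.

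For NIL-Bph6 at 48 h the count was 5124, with 2677 up and 2447 down, and 2235 up and 3098 down with median centring. Falls also outnumbered rises with quantile normalization (2775 and 2560), the stricter intensity filter (2284 and 2159), and without NIL-Bph6 48 h replicate 1 (2185 and 1993) or 3 (2015 and 1976). The count was 3350 without NIL-Bph6 0 h replicate 1 and 11378 with array weights. It was 2106 when a change of at least 2-fold was also required. In NIL-Bph6 the group means of ICL (8.30 ± 0.22 against 4.38 ± 0.28), EXPA29 (5.94 ± 0.57 against 2.21 ± 0.32), CSLA9 (8.18 ± 0.42 against 5.61 ± 1.09) and Chib3H-a (9.20 ± 0.59 against 5.41 ± 0.52) lay partly under 5.78 (SD), where folds are imprecise. Some alternative ended the calls of these genes, with a highest adjusted p of KS6 at 0.0782 and EXPA29 at 0.103 without NIL-Bph6 48 h replicate 1. OsrcaA1 reached 0.136 and CYCB2 0.141 without NIL-Bph6 0 h replicate 1. LEA19 reached 0.111 without NIL-Bph6 48 h replicate 2.

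In NIL-Bph6-RNAi at 48 h, CBF3 rose by 7.27 ± 0.59 (adjusted p = 5.66e-07), DREB1B by 6.54 ± 0.35 (adjusted p = 2.34e-08), ICL by 5.21 ± 0.53 (adjusted p = 4.64e-06) and BURP16 (LOC4348595) by 4.94 ± 0.50 (adjusted p = 4.11e-06). The heat shock factor gene HSF2 (LOC4346229) changed by -4.19 ± 0.63 (adjusted p = 0.000124) and BURP2 (LOC4338119) by -3.12 ± 0.49 (adjusted p = 0.000173). The laccase gene LAC4 (LOC4327500) changed by -2.85 ± 0.60 and CRSH2 (LOC4337890) by -2.70 ± 0.89. In the phenylpropanoid list, 10 of 34 rose and 11 fell, or 12 and 14 adjusted over the list alone, with the laccase gene LAC19 (LOC4351005) at 3.87 ± 0.94. The phenylpropanoid list had camera adjusted p = 0.758, and 0.937 with an estimated correlation.

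The jasmonate list shifted up in this line: 19 of 32 rose and 1 fell, or 21 and 1 adjusted over the list alone, with BHLH148 at 4.26 ± 0.40 and JAZ9 at 3.95 ± 0.60. Camera gave the jasmonate list adjusted p = 1.97e-05, and 0.62 with an estimated correlation. For salicylate signalling 11 of 17 rose and 2 fell, or 11 and 2 adjusted over the list alone. For the salicylate list camera gave adjusted p = 0.000447, and 0.62 with an estimated correlation. In the WRKY list 5 of 6 rose and 0 fell, or 5 and 0 adjusted over the list alone, with WRKY24 at 4.17 ± 0.49 and WRKY71 at 3.91 ± 0.25. The WRKY list had camera adjusted p = 0.000824, and 0.62 with an estimated correlation. Of the phytoalexin genes, 13 of 17 rose and 0 fell, or 14 and 0 adjusted over the list alone, with the diterpene synthesis genes CPS4 (LOC4335090) at 3.16 ± 0.80 (adjusted p = 0.00609) and KS4 (LOC4335094) at 2.91 ± 0.76. Camera gave the phytoalexin list adjusted p = 0.00376, and 0.72 with an estimated correlation. Of the pathogenesis-related genes, 14 of 23 rose and 4 fell, or 14 and 4 adjusted over the list alone, with the chitinase genes Chib3H-a at 2.69 ± 0.53 and Cht-3 (LOC4342114) at 2.13 ± 0.45. For the pathogenesis-related list camera gave adjusted p = 0.0317, and 0.674 with an estimated correlation. In calcium signalling 33 of 76 rose and 12 fell, or 35 and 14 adjusted over the list alone, CML31 at 3.77 ± 0.37 among them. The calcium list had camera adjusted p = 0.0173, and 0.62 with an estimated correlation. In the dehydration list 13 of 32 rose and 1 fell, or 14 and 2 adjusted over the list alone, with ABA8OX1 at 3.85 ± 0.26. Camera gave the dehydration list adjusted p = 0.0234, and 0.62 with an estimated correlation.

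The cell cycle, cell wall, light reaction and carbon fixation lists shifted down in NIL-Bph6-RNAi. For histones and cell cycle 4 of 89 rose and 33 fell, or 4 and 38 adjusted over the list alone, with CYCB2 at -2.69 ± 0.71 (adjusted p = 0.00783) and the kinesin gene KIN10A (LOC4331094) at -3.07 ± 0.82 (adjusted p = 0.00862). For the cell cycle list camera gave adjusted p = 0.000596, and 0.713 with an estimated correlation. In the cell wall list 6 of 65 rose and 26 fell, or 6 and 32 adjusted over the list alone, with CSFL8 (LOC4343552) at -2.43 ± 0.47 and, rising, BC1L9 at 3.94 ± 0.38 and BC1L6 (LOC4343844) at 3.57 ± 0.61. The cell wall list had camera adjusted p = 0.00311, and 0.707 with an estimated correlation. In the light reactions 0 of 14 rose and 9 fell, or 0 and 9 adjusted over the list alone, PSB28 at -1.70 ± 0.28 among them. Camera gave the light reaction list adjusted p = 0.000544, and 0.62 with an estimated correlation. In carbon fixation and chlorophyll synthesis 0 of 21 rose and 14 fell, or 0 and 15 adjusted over the list alone, with PORA (LOC4337415) at -1.55 ± 0.16. For the carbon fixation list camera gave adjusted p = 2.82e-05, and 0.62 with an estimated correlation. Called vascular, epidermis and reference genes mostly fell too, in lists that did not pass in camera, whereas the 5 called root markers rose. Of vascular markers 2 of 13 rose and 7 fell, or 3 and 9 adjusted over the list alone, with a median of -0.61. The vascular list had camera adjusted p = 0.175, and 0.707 with an estimated correlation. Of epidermis markers 0 of 12 rose and 5 fell, or 0 and 5 adjusted over the list alone. Camera gave the epidermis list adjusted p = 0.252, and 0.738 with an estimated correlation. Of the reference genes 2 of 26 rose and 10 fell, or 3 and 10 adjusted over the list alone. For the reference list camera gave adjusted p = 0.136, and 0.784 with an estimated correlation. The count was 10911, with 5464 up and 5447 down, nearly equal numbers whose order changed in several settings, such as 5040 and 5747 with median centring. It ranged from 8176 to 10314 with 1 array left out, and was 5395 when a change of at least 2-fold was also required. Group means (SD) partly under 5.78 applied to CBF3 (11.65 ± 0.41 against 4.38 ± 1.67), ICL (9.03 ± 1.12 against 3.82 ± 0.69), HSF2 (2.0 ± 0.49 against 6.19 ± 0.38), LAC19 (8.76 ± 1.12 against 4.90 ± 2.04), KS4 (8.39 ± 0.87 against 5.48 ± 0.38), Chib3H-a (8.15 ± 0.84 against 5.46 ± 0.94), KIN10A (5.13 ± 2.20 against 8.21 ± 1.18) and BC1L6 (7.87 ± 0.16 against 4.30 ± 1.71). Genes that lost their call in some alternative had a highest adjusted p of CRSH2 at 0.149 without NIL-Bph6-RNAi 48 h replicate 3. KIN10A reached 0.0557 with only the compared groups in the fit.

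Of the probe sets that rose in NIL-Bph6 at 48 h, 1429 of 2677 also rose in NIL-Bph6-RNAi, where independent lists would share 447, and 1490 of 2447 fell in both, against 407. A further 338 rose in NIL-Bph6 and fell in NIL-Bph6-RNAi, where chance gives 445, and 16 did the reverse, against 408. No arrays were shared, and across probe sets the responses correlated at r = 0.343.

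At 48 h, H2B.10 was higher in NIL-Bph6 than in NIL-Bph6-RNAi by 3.06 ± 0.35 (adjusted p = 8.91e-05), CYCB2 by 3.74 ± 0.71 (adjusted p = 0.00287) and KIN10A by 4.05 ± 0.82 (adjusted p = 0.00431). EXPA29 and the endoglucanase gene GLU12 (LOC4347660) were higher by 3.76 ± 1.11 and 3.40 ± 0.83, and the zinc finger gene C3H23 (LOC4332723) by 4.33 ± 0.76. Lower were Cht1 at -2.88 ± 0.65 (adjusted p = 0.00775), BGLU13 at -1.86 ± 0.29, JAMYB (LOC4351131) at -1.78 ± 0.33 (adjusted p = 0.00256), the metallothionein gene MT-1-4b (LOC4352582) at -1.76 ± 0.46 and JAZ5 (LOC4335698) at -1.75 ± 0.29.

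In the cell cycle list 49 of 89 were higher and 1 was lower, or 62 and 1 adjusted over the list alone. The cell cycle list had camera adjusted p = 2.37e-14, and 0.62 with an estimated correlation. In the cell wall list 23 of 65 were higher and 1 was lower, or 28 and 2 adjusted over the list alone. Camera gave the cell wall list adjusted p = 4.51e-05, and 0.62 with an estimated correlation. The meristem, vascular and epidermis lists shifted up in NIL-Bph6 too. The root list did not, since 0 of 10 were higher and 0 were lower, or 0 and 0 adjusted over the list alone, with a median of -0.28. For the root list camera gave adjusted p = 0.291, and 0.624 with an estimated correlation. In the meristem list 5 of 16 were higher and 2 were lower, or 7 and 2 adjusted over the list alone, GRF10 at 2.97 ± 0.36 and GRF6 at 2.89 ± 0.38 among the former. The meristem list had camera adjusted p = 0.0236, and adjusted p = 0.62 with an estimated correlation. In the vascular list 6 of 13 were higher and 0 were lower, or 6 and 1 adjusted over the list alone, with BC1L2 (LOC4333115) at 2.13 ± 0.60 and IRX9 (LOC4344394) at 1.53 ± 0.39. Camera gave the vascular list adjusted p = 0.0457, and 0.62 with an estimated correlation. In the epidermis list 2 of 12 were higher and 0 were lower, or 6 and 0 adjusted over the list alone, with KCS20 (LOC4348632) at 2.54 ± 0.37. For the epidermis list camera gave adjusted p = 0.0326, and 0.62 with an estimated correlation. Of the reference genes, 10 of 26 were higher and 1 was lower, or 12 and 2 adjusted over the list alone, and of the former 9 were tubulin genes such as TUB2 (LOC4331315) at 1.93 ± 0.31 and TUB1 (LOC4326917) at 1.32 ± 0.23. The reference list had camera adjusted p = 0.00586, and adjusted p = 0.636 with an estimated correlation. For ribosomal proteins 2 of 25 were higher and 0 were lower, or 2 and 0 adjusted over the list alone, with RPS26 (LOC4327570) at 0.52 ± 0.13. Camera gave the ribosomal list adjusted p = 0.0165, and adjusted p = 0.784 with an estimated correlation.

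Shifted down in NIL-Bph6 at 48 h was jasmonate signalling, where 1 of 32 was higher and 10 were lower, or 1 and 14 adjusted over the list alone. For the jasmonate list camera gave adjusted p = 0.000156, and adjusted p = 0.624 with an estimated correlation. Salicylate signalling shifted down too, where 0 of 17 were higher and 3 were lower, or 1 and 7 adjusted over the list alone, among them NH3 at -0.96 ± 0.17. The salicylate list had camera adjusted p = 0.0212, and adjusted p = 0.62 with an estimated correlation. For nitrogen remobilisation 0 of 29 were higher and 2 were lower, or 0 and 2 adjusted over the list alone, with GDH2 (LOC4336554) at -0.88 ± 0.21. Camera gave the nitrogen list adjusted p = 0.012, and adjusted p = 0.62 with an estimated correlation. For the light reactions 0 of 14 were higher and 1 was lower, or 0 and 1 adjusted over the list alone, namely petC (LOC4343570) at -0.35 ± 0.10. For the light reaction list camera gave adjusted p = 0.0293, and adjusted p = 0.707 with an estimated correlation. In limma 4449 probe sets differed, 2878 higher and 1571 lower, and 2289 and 2584 with median centring. Without NIL-Bph6 48 h replicates 1 and 3 the count was 2911 and 2641, without NIL-Bph6-RNAi 48 h replicate 3, the array farthest from other groups, 2585, and with only the compared groups in the fit 2808. It was 2240 when a change of at least 2-fold was also required. The light reaction call ended with quantile normalization, at adjusted p = 0.459, the vascular call with all probe sets as members, at 0.0585. Group means (SD) partly under 5.78 applied to KIN10A (9.18 ± 0.39 against 5.13 ± 2.20), EXPA29 (5.94 ± 0.57 against 2.18 ± 2.17), GLU12 (7.36 ± 0.41 against 3.96 ± 2.02), C3H23 (7.73 ± 0.45 against 3.40 ± 2.19), Cht1 (4.89 ± 1.29 against 7.77 ± 0.43), GRF10 (8.16 ± 0.23 against 5.19 ± 0.25) and BC1L2 (7.33 ± 0.43 against 5.21 ± 0.70). Genes that lost their call in some alternative had a highest adjusted p of EXPA29 at 0.119, BC1L2 at 0.0967, GDH2 at 0.0575 and petC at 0.14 without NIL-Bph6 48 h replicate 1. GLU12 reached 0.0607, MT-1-4b 0.0962 and IRX9 0.0728 without NIL-Bph6-RNAi 48 h replicate 3. RPS26 reached 0.0595 without NIL-Bph6 48 h replicate 3.

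**Figure D2:**
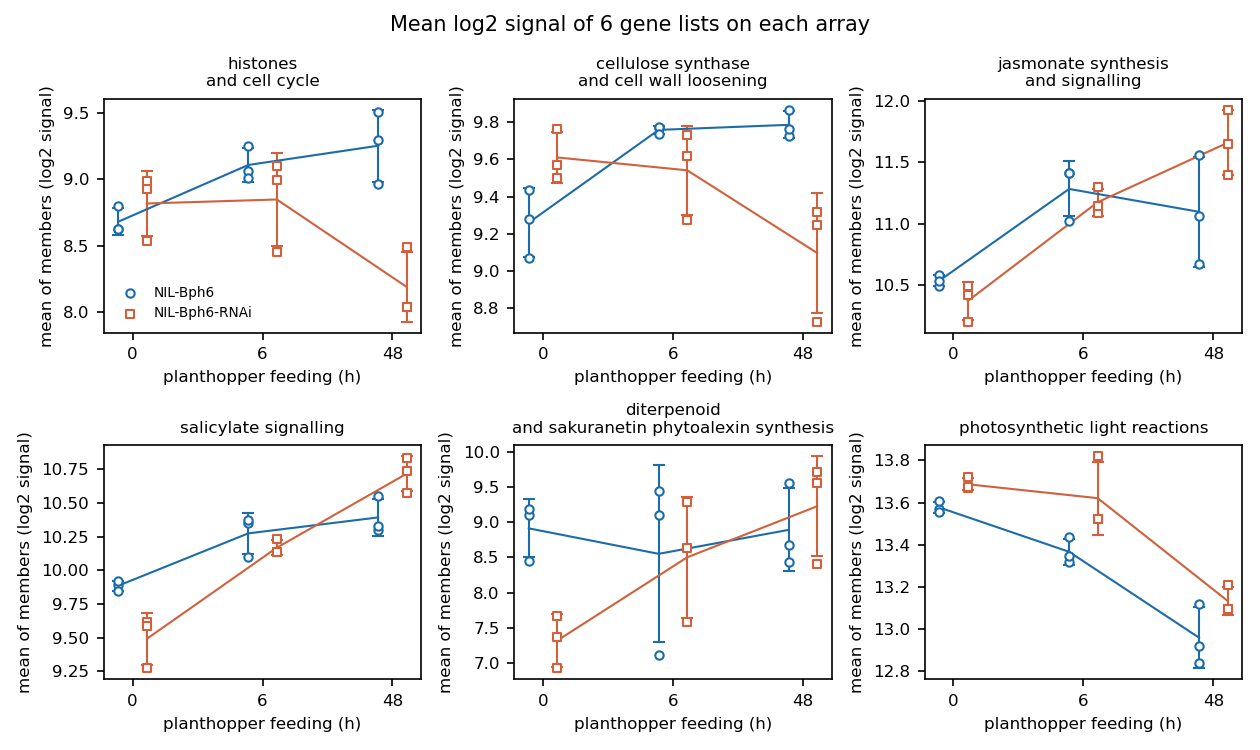
Mean log2 signal of the measured members of 6 gene lists on each array against hours of planthopper feeding, with points for arrays, lines through group means and bars for SD (n = 3). At 48 h the cell cycle list lies higher on each NIL-Bph6 array than on each NIL-Bph6-RNAi array.

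Over 48 h, the cyclin gene CYCB2 changed by 2.37 in NIL-Bph6 and -2.69 in NIL-Bph6-RNAi, a difference of 5.06 ± 1.01 (adjusted p = 0.00723). KIN10A differed by 5.28 ± 1.17 (adjusted p = 0.0111), GLU12 by 4.50 ± 1.18 (adjusted p = 0.0223) and GRF10 by 3.90 ± 0.51 (adjusted p = 0.0038). C3H23 differed by 6.25 ± 1.08, with means in NIL-Bph6 of 4.63 ± 0.30 at 0 h and 7.73 ± 0.45 at 48 h (SD). The expansin gene EXPB17 (LOC4336479) differed by 3.41 ± 0.83 (adjusted p = 0.0162). Of the cell cycle genes, 40 of 89 changed more upward in NIL-Bph6 and 0 more downward, or 53 and 2 adjusted over the list alone. The cell cycle list had camera adjusted p = 2.83e-11, and adjusted p = 0.62 with an estimated correlation. Of the cell wall genes 23 of 65 changed more upward and 0 more downward, or 34 and 4 adjusted over the list alone. Camera gave the cell wall list adjusted p = 2.93e-08, and adjusted p = 0.62 with an estimated correlation.

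As whole lists, meristem, vascular, epidermis and reference genes differed in the same direction. Root markers had a median of -0.64, and 0 of 10 changed more upward and 2 more downward, or 0 and 2 adjusted over the list alone. For the root list camera gave adjusted p = 0.16, and adjusted p = 0.62 with an estimated correlation. In the meristem list 5 of 16 changed more upward and 2 more downward, or 5 and 2 adjusted over the list alone. The meristem list had camera adjusted p = 0.0326, and adjusted p = 0.62 with an estimated correlation. The 2 members with the lower change in NIL-Bph6 were HOS59 at -0.37 and OSH45 at -0.69, and GRF6 at 3.41 ± 0.54 was among the 5 with the higher. For vascular markers 4 of 13 changed more upward and 0 more downward, or 9 and 2 adjusted over the list alone, with BC1L2 at 3.01 ± 0.85 and IRX9 at 1.96 ± 0.55. Camera gave the vascular list adjusted p = 0.0205, and adjusted p = 0.62 with an estimated correlation. For epidermis 4 of 12 changed more upward and 0 more downward, or 5 and 0 adjusted over the list alone, with KCS20 at 2.92 ± 0.52. For the epidermis list camera gave adjusted p = 0.0187, and adjusted p = 0.62 with an estimated correlation. For reference genes 6 of 26 changed more upward and 0 more downward, or 11 and 1 adjusted over the list alone, TUB2 at 2.0 ± 0.43 among them. The reference list had camera adjusted p = 0.0202, and adjusted p = 0.683 with an estimated correlation. The germin-like genes GER8 (LOC4325743) and GER4 (LOC4327911) differed by 2.53 ± 0.48 and 2.31 ± 0.39.

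CBF3, DREB1B and some genes of the jasmonate, salicylate and WRKY lists rose less in NIL-Bph6 than in NIL-Bph6-RNAi. CBF3 rose by 4.29 and 7.27, a difference of -2.98 ± 0.84 (adjusted p = 0.032), but its mean of 4.38 ± 1.67 (SD) in NIL-Bph6-RNAi at 0 h lay under 5.78, so the size is imprecise. DREB1B rose by 4.32 and 6.54, a difference of -2.21 ± 0.50 (adjusted p = 0.0119). The germin-like gene GLP2 differed by -2.28 ± 0.50 (adjusted p = 0.0105) and MT1B by -2.18 ± 0.53 (adjusted p = 0.0159). In NIL-Bph6 MT1B stood at 11.93 ± 0.62 at 0 h and 12.18 ± 0.66 at 48 h (SD, n = 3). For CBF3, DREB1B and MT1B much of the difference lay in the start, with NIL-Bph6 minus NIL-Bph6-RNAi at 2.19 (adjusted p = 0.0887), 1.80 (0.0137) and 1.98 (0.0106) at 0 h. At 48 h the lines differed by -0.78, -0.415 and -0.21 for these genes, none past the test (adjusted p = 0.442, 0.501 and 0.785). WRKY71 rose by 1.97 and 3.91, a difference of -1.94 ± 0.36 (adjusted p = 0.00566), having started higher in NIL-Bph6, and WRKY76 (LOC4347069) differed by -1.93 ± 0.54 (adjusted p = 0.0293). Among jasmonate genes, OPDAR1 (LOC4340490) differed by -1.89 ± 0.49 (adjusted p = 0.0221) and JAZ5 by -1.88 ± 0.41 (adjusted p = 0.011). In the jasmonate list 0 of 32 changed more upward and 8 more downward, or 0 and 15 adjusted over the list alone. Camera gave the jasmonate list adjusted p = 0.000544, and adjusted p = 0.638 with an estimated correlation. In the salicylate list 0 of 17 changed more upward and 7 more downward, or 0 and 10 adjusted over the list alone. For the salicylate list camera gave adjusted p = 0.00145, and adjusted p = 0.62 with an estimated correlation. In the WRKY list 0 of 6 changed more upward and 2 more downward, or 0 and 5 adjusted over the list alone. The WRKY list had camera adjusted p = 0.0236, and adjusted p = 0.62 with an estimated correlation. The phytoalexin list had a median difference in response of -1.96, after 1.63 between the lines at 0 h and -0.33 at 48 h, while 0 of 17 changed more upward and 0 more downward, or 0 and 0 adjusted over the list alone. Camera gave the phytoalexin list adjusted p = 0.000596, and adjusted p = 0.707 with an estimated correlation. For nitrogen remobilisation 0 of 29 changed more upward and 3 more downward, or 0 and 5 adjusted over the list alone, with the ammonium transporter gene AMT1-1 (LOC4336365) at -1.41 ± 0.36. For the nitrogen list camera gave adjusted p = 0.0204, and adjusted p = 0.62 with an estimated correlation.

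In limma 3676 probe sets differed in response at 48 h, 2337 with the higher change in NIL-Bph6 and 1339 with the lower, and 2809 (76.4%) of them changed by more in NIL-Bph6-RNAi. Their median size of change was 0.48 in NIL-Bph6 and 1.11 in NIL-Bph6-RNAi. By their calls in each line, 1453 fell in NIL-Bph6-RNAi and were not called in NIL-Bph6, and 950 rose in NIL-Bph6-RNAi and were not called in NIL-Bph6. A further 413 rose in NIL-Bph6 and were not called in NIL-Bph6-RNAi, 338 rose in NIL-Bph6 and fell in NIL-Bph6-RNAi, and 181 rose in both, less in NIL-Bph6. The count was 2181 without NIL-Bph6 0 h replicate 3, 1972 without NIL-Bph6 48 h replicate 3, 1643 without NIL-Bph6-RNAi 0 h replicate 2 and 2056 without NIL-Bph6-RNAi 48 h replicate 3. It was 6634 with array weights and 2391 with the 3' to 5' covariate. With median centring the median over all probe sets was -0.10. In NIL-Bph6-RNAi the means at 48 h of C3H23, KIN10A, GLU12, GRF10 and BC1L2, given above, also lay under 5.78, and these sizes are imprecise. The means in NIL-Bph6 at 48 h and 0 h (SD) lay partly under 5.78 for GLU12 (7.36 ± 0.41 against 5.10 ± 0.13), GRF10 (8.16 ± 0.23 against 5.32 ± 0.66) and BC1L2 (7.33 ± 0.43 against 5.0 ± 0.94). Genes whose call some alternative ended had a highest adjusted p of GLU12 at 0.0628, EXPB17 at 0.0531, BC1L2 at 0.0908, IRX9 at 0.0905, WRKY76 at 0.0881, OPDAR1 at 0.0708 and AMT1-1 at 0.0583 without NIL-Bph6-RNAi 0 h replicate 2. CBF3 reached 0.0835 without NIL-Bph6 0 h replicate 3.

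**Figure D3:**
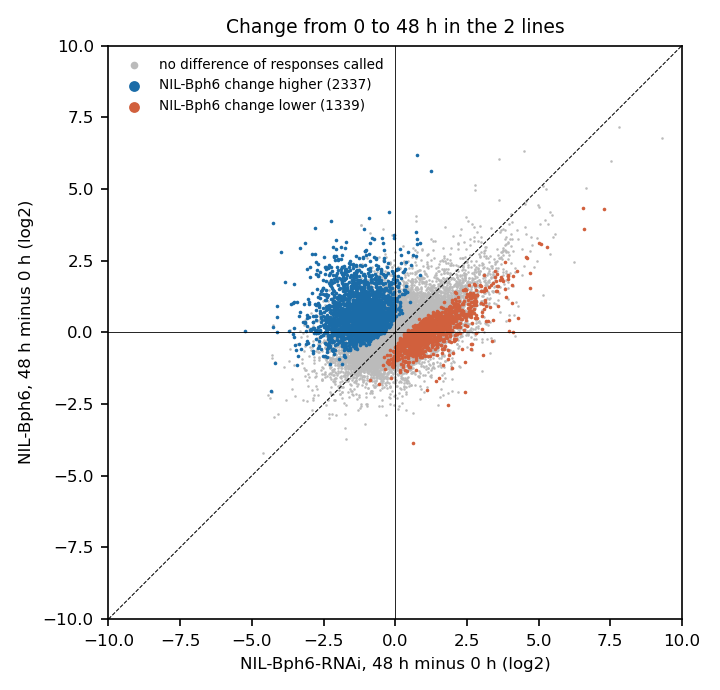
Log2 change from 0 to 48 h in NIL-Bph6 against that in NIL-Bph6-RNAi for 32732 probe sets, with the dashed line marking equal change. Probe sets whose responses differed are coloured, 2337 with the higher change in NIL-Bph6 and 1339 with the lower.

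Of 270 list tests, 76 passed with the preset correlation of 0.01 and 0 of these with an estimated one. Cytokinin metabolism, exocyst and secretion, protease inhibitors, heat shock proteins, gibberellin metabolism, sugar and starch metabolism, the circadian clock, root markers and pollen markers passed in none of the 9 comparisons. In NIL-Bph6-RNAi at 48 h single members of these lists still changed, but so did 7019 of 16404 genes, 3512 up and 3507 down. In the cytokinin list 11 of 27 rose and 6 fell, or 11 and 6 adjusted over the list alone, with LOGL3 (LOC4331344) at 2.32 ± 0.31 and RR1 (LOC4335937) at -2.12 ± 0.33. The cytokinin list had camera adjusted p = 0.334, and 0.638 with an estimated correlation. In the secretion list 2 of 10 rose and 4 fell, or 3 and 4 adjusted over the list alone, with SCAMP4 (LOC4333331) at 1.26 ± 0.19. Camera gave the secretion list adjusted p = 0.618, and 0.849 with an estimated correlation. Of the protease inhibitors 6 of 9 rose and 0 fell, or 7 and 0 adjusted over the list alone. For the protease inhibitor list camera gave adjusted p = 0.0986, and 0.624 with an estimated correlation. Of the heat shock genes 13 of 47 rose and 7 fell, or 13 and 7 adjusted over the list alone. The heat shock list had camera adjusted p = 0.428, and 0.849 with an estimated correlation. In the gibberellin list 5 of 15 rose and 3 fell, or 5 and 5 adjusted over the list alone. Camera gave the gibberellin list adjusted p = 0.784, and 0.849 with an estimated correlation. In the sugar list 9 of 53 rose and 15 fell, or 12 and 15 adjusted over the list alone. For the sugar list camera gave adjusted p = 0.508, and 0.707 with an estimated correlation. Of the clock genes 3 of 12 rose and 0 fell, or 3 and 0 adjusted over the list alone. The clock list had camera adjusted p = 0.451, and 0.849 with an estimated correlation. Of root markers 5 of 10 rose and 0 fell, or 5 and 0 adjusted over the list alone. Camera gave the root list adjusted p = 0.235, and 0.62 with an estimated correlation. Of pollen markers 0 of 8 rose and 2 fell, or 0 and 2 adjusted over the list alone. For the pollen list camera gave adjusted p = 0.428, and 0.707 with an estimated correlation. The cytokinin gene LOG (LOC4324445) differed in response at 48 h by -1.51 ± 0.33 (adjusted p = 0.0105), and SCAMP3 by 1.37 ± 0.25 (adjusted p = 0.00525). Not tested, with under 5 measured members, were callose synthesis (0), terpene synthases (1), NB-LRR resistance proteins (0) and seed markers (4). Median, mean and test differed in sign in none of the 76 list tests that passed.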

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

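The tests with array weights, on the mean of both responses and on class I KNOX genes were chosen after the result was seen, and the other tests of this part before. In limma, a direct test of the difference between the responses of the lines at 48 h called 40 of 89 cell cycle and 23 of 65 cell wall genes, all with the higher change in NIL-Bph6. Of the named genes, C3H23 differed by 6.25, KIN10A by 5.28, CYCB2 (LOC4342121) by 5.06, GLU12 by 4.50, GRF10 by 3.90, TBL3 by 3.86, CAD7 by 3.80, RSS1 by 3.70, EXPB17 by 3.41 and GRF6 by 3.41. BC1L2 differed by 3.01, KCS20 by 2.92, GER8 by 2.53, GER4 by 2.31, TUB2 by 2.0, IRX9 by 1.96, TUB6 by 1.93, LAC23 by 1.88, SCAMP3 by 1.37, Hpt5 by 1.35 and LTPL1 by 1.25. On the other side lay CBF3 at -2.98, GLP2 at -2.28, DREB1B at -2.21, MT1B at -2.18, GH3.2 at -2.17, NAS1 at -2.17, ERG1 at -2.17 and PP2C61 at -2.10. WRKY71 at -1.94, WRKY76 at -1.93, OPDAR1 at -1.89, JAZ5 at -1.88, LOG at -1.51, AMT1-1 at -1.41, SCAMP4 at -1.24 and GLN1-2 at -1.04 had the lower change in NIL-Bph6 as well. NAS1 and GH3.2 had started higher in NIL-Bph6, by 2.15 and 1.94, nearly the whole of their difference, and PP2C61 by 1.17. Some alternative ended the calls of LAC23 and Hpt5, each in 12 alternatives, with adjusted p up to 0.121 and 0.134. The same befell GLN1-2 (up to 0.0877), GH3.2 (0.0694), ERG1 (0.0651) and TUB6 (0.0597).

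By the same test the responses differed for 2 probe sets at 6 h and 3676 at 48 h. No list call held with an estimated correlation, where each adjusted p was 0.62 or higher. With the preset one, the list medians that differed at 6 h were -1.55 for phytoalexin synthesis, 0.49 for cell wall, 0.36 for cell cycle, 0.38 for meristem and 0.36 for epidermis. At 48 h they were -1.96 for phytoalexin synthesis, -1.66 for WRKY genes, -0.75 for jasmonate, -0.62 for salicylate and -0.41 for nitrogen remobilisation. Of these, the phytoalexin, WRKY and salicylate lists had started higher in NIL-Bph6, by medians of 1.63, 0.68 and 0.28. On the other side they were 1.05 for cell cycle, 0.84 for cell wall, 0.83 for meristem, 0.82 for vascular, 0.76 for epidermis and 0.25 for reference genes, none of them past the test with an estimated correlation. The cell wall list had started lower in NIL-Bph6, by -0.37. At 6 h much of the phytoalexin and cell cycle differences lay in 1 array each. For the difference of responses at 48 h, 2 of 100 splits of the arrays, the real one included, gave as many, the highest other giving 3711. The splits regrouped the lines at each time and so removed the line difference itself. Their share therefore cannot exclude chance for a difference of responses. At 6 h 4 of 100, the real one included, gave 2 or more, and for the same reason this share does not exclude chance. The highest other gave 29, several times the real count. That split kept both lines together at 0 h but mixed them at 6 h, so it held the difference between the lines at 0 h. The count was also 0 without the trend and without any 1 of 7 arrays, so the 6 h result stays weak. The split with 3711 kept both lines together at 48 h but mixed them at 0 h. Without the 10 other splits that kept the lines at 48 h, the highest other count was 1. The count at 48 h thus followed the difference between the lines at that time.

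For each of the 7 comparisons of 2 groups, the real split was 1 of 10, too few for a share under 0.05. The real counts and the highest of the other splits were 460 and 1, 282 and 0, and 4449 and 2 for the lines at 0, 6 and 48 h. They were 1675 and 0, and 5124 and 1, for NIL-Bph6 at 6 h and 48 h, and 1736 and 0, and 10911 and 0, for NIL-Bph6-RNAi.

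Over the 89 cell cycle genes the median change at 48 h was 0.41 in NIL-Bph6 and -0.53 in NIL-Bph6-RNAi. A single array as the whole cause is argued against by the lowest median difference with any of 12 arrays left out, 0.97, and array scaling by the lower of the medians under quantile normalization and median centring, 1.02. More shoot meristem tissue in the NIL-Bph6 samples at 48 h may be a source, and it stays open, since 1 class I KNOX gene (OSH43) was measured, at a low mean of 5.19 and with a difference of 1.22. The GRF genes of the meristem list differed in that direction, while the class II KNOX genes HOS59 and OSH45 did the opposite. A biological difference between the lines in growth under feeding stays open too, as untested, because no samples without insects at 48 h were analysed.

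At 48 h the count was 2.13 times as high in NIL-Bph6-RNAi as in NIL-Bph6. A single array is argued against by the lowest count for NIL-Bph6-RNAi, 8176, and scaling by a ratio of 2.02. With the 3' to 5' covariate the ratio was 2.39, but this cannot decide on RNA quality. The covariate averaged actin, GAPDH, EF1a and cyclophilin and varied mostly with GAPDH. By array GAPDH ran from -0.82 to 5.90, and cyclophilin from 0.97 to 1.60. Uneven precision of the arrays stays open. Array weights brought the ratio to 0.967, by a higher count in NIL-Bph6, but they gave NIL-Bph6 0 h replicate 1 88.8% of the weight of its group, so that this test rests on effectively 1 array at 0 h and decides nothing. A larger response of the same genes in NIL-Bph6-RNAi is open as well. Of 10107 probe sets called for the mean of both responses, 71.5% changed more in that line, with medians of 0.86 against 0.53. Over probe sets called in NIL-Bph6 the medians were 0.58 against 0.89. Neither decides this, since the first choice admits changes of NIL-Bph6-RNAi alone and the second favours NIL-Bph6.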

How the results depend on the processing

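Array weights, the 3' to 5' covariate and the offset were chosen after the data had been seen, and the other settings before. No named gene called in limma reversed direction in the settings run for named genes, and the cause was not tested where a count moved, except as stated. The balance of rises and falls did turn for some counts. For the lines it went from 282 higher and 178 lower to 113 and 120 at 0 h without NIL-Bph6 0 h replicate 3, and from 2878 and 1571 to 2289 and 2584 at 48 h with median centring. For NIL-Bph6 at 6 h it went from 1152 up and 523 down to 4260 and 4337 with array weights. At 48 h it went from 2677 and 2447 to 2235 and 3098 with median centring, and also turned with quantile normalization, the stricter filter and without NIL-Bph6 48 h replicate 1 or 3. For NIL-Bph6-RNAi at 48 h, 5464 and 5447 are nearly equal, and the order turned with quantile normalization, median centring, the stricter filter, the block, array weights, the 2-fold minimum and without NIL-Bph6-RNAi 48 h replicate 2 or 3. With array weights the counts were 5247, 727, 8597, 11378 and 3941 for the lines at 0 h and 6 h, NIL-Bph6 at 6 h and 48 h and NIL-Bph6-RNAi at 6 h. For the differences of responses they were 1066 at 6 h and 6634 at 48 h. NIL-Bph6 0 h replicate 1 then weighed 8.14 and the other arrays 0.38 to 2.24. With the covariate the counts were 221 for the lines at 0 h, and 1 and 2391 for the differences of responses at 6 h and 48 h. With only the compared groups in the fit, which leaves fewer arrays for the spread, they were 289 and 2808 for the lines at 0 h and 48 h, and 5 for the difference of responses at 6 h. Without the trend the last was 0, with 4491 at an unadjusted p under 0.05. Requiring a change of at least 2-fold, which lowers a count by construction, gave 2240 for the lines at 48 h, 865 and 2106 for NIL-Bph6 at 6 h and 48 h, and 828 and 5395 for NIL-Bph6-RNAi. Without 1 array at a time the counts ran from 225 to 850, 179 to 233 and 2585 to 3983 for the lines at 0, 6 and 48 h. They ran from 792 to 1412 and 3350 to 5274 for NIL-Bph6, from 669 to 1498 and 8176 to 10314 for NIL-Bph6-RNAi, and from 0 to 53 and 1643 to 4745 for the differences of responses. Quantile normalization, median centring, both filters, the offset and the replicate block left each count within 1.5 times its value. With the block the counts for the differences of responses were 2 and 3872, and arrays with the same number in different groups were not alike, with a median correlation of deviations of 0.006 over 45 pairs.

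Of the 76 list calls, 0 passed with an estimated correlation, where the lowest adjusted p was 0.62. With quantile normalization 70 were kept and 6 lost, with all probe sets as members 73 kept and 3 lost, and with the block 76 kept. Of 347 calls of named genes, 56 were lost with only the compared groups in the fit, 49 without the trend, 14 with the block, 13 with median centring, 9 with quantile normalization and 0 with the offset. Leaving out arrays ended 511 of 2442. Signals near the floor limit what can be seen of genes with means under 5.78, and 3 arrays per group limit all calls.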

Other observations

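The tests of this part were chosen before their results were seen. Some genes kept their difference between the lines at each time. Of the 460 probe sets that differed at 0 h, 140 were called in the same direction at 6 h and 48 h, 51 higher and 89 lower in NIL-Bph6, and 235 were called at neither later time. Cht1 was among the former, at -2.86, -3.67 and -2.88 at 0, 6 and 48 h. Of the 178 probe sets lower in NIL-Bph6 at 0 h, 117 were also lower at 48 h, where independent lists would share 8.54, and of the 282 higher ones 81 were, against 24.8.

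Further members of families given in the report rose in 1 line or both. The cold-response gene DREB1G rose by 3.49 in NIL-Bph6 and 3.23 in NIL-Bph6-RNAi at 6 h. The dehydration genes RAB21 and LEA19 rose by 2.84 and 2.52 in NIL-Bph6-RNAi at 6 h, and by 2.0 and 2.08 in NIL-Bph6 at 48 h. Leaving out NIL-Bph6-RNAi 0 h replicate 2 ended the call of LEA19 at 6 h (adjusted p = 0.112). Without NIL-Bph6 48 h replicate 2 those of RAB21 and LEA19 at 48 h ended (0.108 and 0.111).

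Called genes at 0 h lay next to each other in the gene order more often than chance gives. Of 251 called genes, 50 had a called neighbour, against a median of 8, a 95th percentile of 14 and a highest value of 27 in 10000 random draws, and 16 among as many genes of the NIL-Bph6-RNAi response at 48 h. Runs were formed of called genes lying at most 5 measured genes apart. Of the 8 longest, 6 lay on chromosome 5, and these held 30 genes. The locus number of Bph6 places that gene on another chromosome. Genome segments that differ between the lines, beside the construct, may thus account for part of the difference before feeding. Of all probe sets called at 0 h, 30.4% were called in the same direction at each time. This lies between the bounds set for fixed differences and a different plant state, so neither was decided. By run, longest first, 6/8, 5/6, 2/5, 4/5, 3/4, 0/3, 1/3 and 0/3 genes were so called.

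Time of day could contribute to changes that both lines shared at 6 h. Of 12 measured clock genes 0 changed in both lines in the same direction in limma, against 370 of 16392 other genes (2.26%; Fisher's exact test, one-sided, p = 1). At that share 0.27 clock genes would be expected, so the list was too small to decide, and an effect of time of day or handling stays open.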
